A study of Homo sapiens with 3 samples.

How the data were processed

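Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where CREB3L2 sits on the genome of VCaP cells, an established human prostate cancer line that responds to androgen. CREB3L2 is a basic leucine zipper transcription factor made as a membrane protein of the endoplasmic reticulum, whose cytosolic part enters the nucleus after cleavage. The series holds 3 samples: 1 CREB3L2 ChIP from cells given ethanol (vehicle), 1 CREB3L2 ChIP from cells given 100 nM dihydrotestosterone (DHT), the potent natural androgen, and 1 input library without antibody. Per the labels, both treatments lasted 2 h and began after 1 day in medium without phenol red that held 10% charcoal-stripped serum, which removes steroid hormones. A peak list was at hand for each of the 2 ChIP samples. Input values were not analysed here.

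Each peak list gives a chromosome, start, end, name and score per peak. Per the file contents, all 5781 vehicle and 7742 DHT peaks carry names of the form written by the peak caller MACS, and 1 list stands for each sample. The version, settings and control of the peak calling are not given in the sources used here, and whether libraries were pooled is also not given in the sources used here. The score in the deposited lists has no header. It is never below 40 and reaches 3100, a range that fits the scaled negative log10 p values of early MACS versions, but no source states this, so it was treated as a score that ranks peaks within 1 list. Per the submitters' processing notes, the build was hg19 and the tools named were CASAVA 1.8.2, Bowtie 0.12.9, SAMtools 1.9.0, Picard and deepTools 3.4.3, with no role or order given. The coordinates fit that build: 0 peaks of either list end beyond an hg19 chromosome, whereas 37 vehicle and 57 DHT peaks end beyond the GRCh38 chromosome of the same name. The lists hold no read counts, so the depth of the libraries is unknown, and a longer list, wider peaks or higher scores can come from a deeper or better enriched library as well as from binding. Scores were therefore not read as a difference in binding between the lists. Counts at a common score, such as 50 or 100, describe each list on its own scale, and rank within a list was used beside them.

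The lists were compared by overlap with bedtools 2.31.1, and a peak had a partner when it shared at least 1 bp with a peak of the other list. Overlapping peaks of both lists were merged into regions. The overlap expected by chance came from 1000 shuffles in which each peak kept its width and chromosome, and from another 1000 in which each peak was moved by 10 to 500 kb along its chromosome, which keeps the regional peak density. The whole-chromosome shuffles may place peaks in assembly gaps. Shares carry Wilson 95% intervals over peaks, which cover counting error only. Peaks are not replicates, and with 1 list per condition no test of DHT against vehicle exists, so no p value is given and each difference between the lists is a difference between 2 libraries. The overlap code was tested on 2 simulated lists of 6000 peaks each, where it recovered 1500 of 1500 planted pairs with 0 disagreements with bedtools.

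Cytogenetic bands and chromosome lengths of hg19 were those shipped with the R packages circlize 0.4.16 and GenomeInfoDb 1.38.1 under R 4.3.3. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Coordinates are hg19 and count from 1. The rule for the peaks the text names was set before the data were examined, as were the comparison design and most alternatives: the 15 shared regions with the best mean rank of score over both lists, and the 8 highest-scoring peaks found in each list alone. The rule as set also asked for the start of a protein-coding gene close by. Without gene positions of the build, that condition was dropped, and positions stand for names. The bins of score rank, the clusters of at least 5 peaks, chained over gaps of up to 20 kb across both lists, the choice of which clusters to name, a score of at least 100 as a mark of strong peaks, the zone within 2 Mb of heterochromatin bands (stained as centromeric, stalk or variable) and dense loci (1 Mb bins with at least 15 peaks in a list) were chosen after the data were examined.

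Alternatives were other rules for a partner, stricter score thresholds, lists of equal length, and lists without dense loci or without peaks near heterochromatin.

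The planned counts of peaks at promoters, of members of 15 fixed gene lists with a nearby peak, and of 17 fixed motifs needed gene positions or sequence of hg19. The gene table at hand was of the GRCh38.p14 assembly, and no genome sequence was used here, so these 3 results were not run, and no peak was assigned to a gene. Genes named beside a band are textbook background on that band, chosen after the values were seen. Results at 1 locus, among them 2 of the 8 highest-scoring peaks found in the vehicle list alone and a test of broad peaks that rested on it, are not reported here.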

Results

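CREB3L2 occupancy in VCaP prostate cancer cells was described by 5781 peaks after vehicle and 7742 peaks after 2 h of 100 nM DHT, with 1 peak list per condition. The series sets CREB3L2 beside androgen signalling, so the question was where CREB3L2 peaks lie without androgen and how the map differs after androgen is added. The DHT list held 1.34 times as many peaks as the vehicle list and covered 3.51 Mb against 2.06 Mb, or 1.70 times as much sequence. The median peak width was 300 bp (quartiles 213 and 530 bp) in the DHT list and 231 bp (183 and 407 bp) in the vehicle list. Read depth is unknown for both libraries. Many peaks sat close to the lowest deposited score of 40: 61.0% of the vehicle and 51.0% of the DHT peaks scored under 50.

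Most peaks were found in 1 list alone. Of the vehicle peaks, 1438 overlapped a DHT peak (24.9%, 95% interval 23.8 to 26.0), and of the DHT peaks, 1380 overlapped a vehicle peak (17.8%, 17.0 to 18.7). With both lists cut to scores of at least 50, the shares were 43.4% and 24.9%. Against the whole other list, 1160 of 2253 vehicle peaks and 2612 of 3793 DHT peaks of such scores had no partner. The 2 lists merged into 12037 regions, of which 1332 were shared (11.1%, 10.5 to 11.6), 4343 were found after vehicle alone and 6362 after DHT alone. The shared set was far larger than chance: whole-chromosome shuffles of the vehicle peaks gave 13.2 ± 3.6 overlapping peaks (SD over 1000 shuffles, at most 24), and moves by 10 to 500 kb gave 31.2 ± 5.5 (at most 52). These counts describe the 2 libraries and have no replicate check.

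The highest-ranked peaks of each list mostly had a partner in the other, whereas the lowest-ranked mostly had none. Among the 100 highest-scoring vehicle peaks, 96.0% had a DHT partner (90.2 to 98.4), and among the 100 highest-scoring DHT peaks, 94.0% had a vehicle partner (87.5 to 97.2). The share fell with rank in both lists, to 7.13% (6.03 to 8.42) for vehicle peaks ranked after the first 4000 and to 4.89% (4.24 to 5.63) for DHT peaks ranked after the first 4000. Shared vehicle peaks had a median score of 69.9 and a median width of 493.5 bp, against 45.1 and 203 bp for vehicle peaks without a partner. Shared DHT peaks had a median score of 98.1 and a median width of 615.5 bp, against 47.2 and 261 bp for the others. In the ranks after the first 500 and up to 1000, 48.0% (43.7 to 52.4) of DHT peaks had a vehicle partner, and 62.4% (58.1 to 66.5) of vehicle peaks had a DHT partner. Of the first 1000 peaks, 61.5% (58.4 to 64.5) were shared in the DHT list and 74.5% (71.7 to 77.1) in the vehicle list. With the DHT list shortened by score to the length of the vehicle list, the vehicle value was 72.8% (70.0 to 75.5). Ranks from lists of different lengths show no change in binding. Across the 1332 shared regions, which are not independent replicates, the scores of the 2 lists had a Spearman rho of 0.53.

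**Figure D1:**
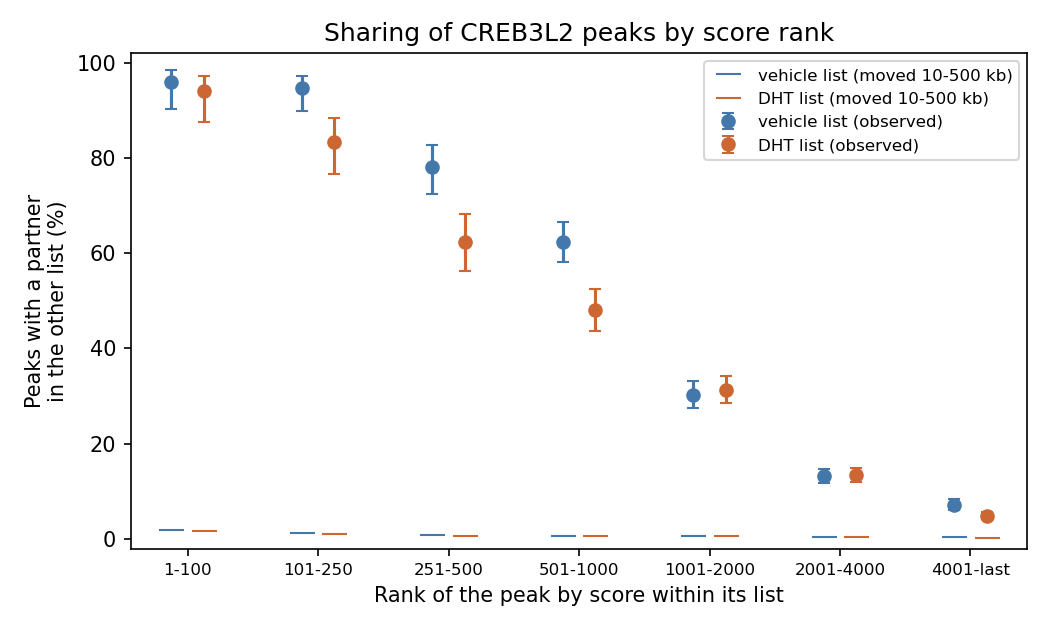
Share of peaks with a partner in the other list (y axis, %) by rank of score within the list (x axis), for the vehicle and DHT lists; points are observed shares with Wilson 95% intervals and dashes are the mean share after moving peaks by 10 to 500 kb. The share falls from 96.0% and 94.0% in the first 100 peaks to 7.13% and 4.89% in the lowest ranks, above the dashes throughout.

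Band 19q13.41 took 5 of the 15 best-ranked shared regions. The region with the best mean rank was chromosome 19 from 52459949 to 52466689, where 3 vehicle peaks (best score 1412) met 1 DHT peak of 6653 bp (score 3100). The DHT peak at 52527281 to 52531869 had the same score, the highest of that list, so the order of these DHT peaks is arbitrary. Further shared regions of this band lay at 52407505 to 52410073, at 52477962 to 52481699, at 52481921 to 52487955 and at 52527281 to 52531869. Band 7p14.1, which holds the T cell receptor gamma locus, took 2 of the 15, at 38298225 to 38304740 and at 38351890 to 38356724 of chromosome 7. The other 8 regions were 883 to 1828 bp long. They lay in 6p22.1 (chromosome 6 from 27027556 to 27028520), 21q21.1 (chromosome 21 from 18807573 to 18808455), 10q22.2 (chromosome 10 from 75503259 to 75504443), 19p13.12 (chromosome 19 from 15596480 to 15597403), 22q11.23 (chromosome 22 from 23877555 to 23878755), 13q34 (chromosome 13 from 111545505 to 111547332), 8q24.3 (chromosome 8 from 146246943 to 146247950) and 15q23 (chromosome 15 from 68212664 to 68213607). The 6p22.1 site ranked 2 of the vehicle and 14 of the DHT list. None of the 15 lay within 2 Mb of a heterochromatin band.

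High-ranked peaks without a partner were more numerous in the DHT list. Among the first 500 peaks by score, 125 DHT peaks (95% interval 21.4 to 29.0%) and 67 vehicle peaks (10.7 to 16.7%) had no partner, and among the first 1000 the numbers were 385 and 255. At a score of at least 100, 679 of 1148 DHT peaks were shared (59.1%, 56.3 to 62.0) and 469 were not, whereas 419 of 476 vehicle peaks were shared (88.0%, 84.8 to 90.6) and 57 were not. Partners of these peaks were sought in the whole other list, which is longer for vehicle peaks. Peaks were counted here, not regions, and 1 shared region can fill several ranks. Several vehicle peaks fell in 79 of the shared regions and several DHT peaks in 45, which can raise the vehicle share. A score can move with depth, so the counts at a common score are not on 1 scale. The highest DHT peak with no vehicle partner lay in 6p21.31 (chromosome 6 from 35689777 to 35692643, score 1060, rank 32), and the nearest vehicle peak was 1125154 bp away. This band also holds FKBP5, a classical androgen-induced gene that encodes a co-chaperone of steroid receptors. The next DHT peaks lay in 10q11.22 (chromosome 10 from 47090071 to 47091041, score 943), 22q11.21 (chromosome 22 from 21496479 to 21502017, score 856) and 6p11.1 (chromosome 6 from 58776134 to 58779971, score 846). Band 6p11.1 is itself stained as centromeric. The remaining 4 of the 8 lay in 6q27 (chromosome 6 from 169028152 to 169029518), 15q26.3 (chromosome 15 from 99342483 to 99345996), 6q23.3 (chromosome 6 from 137692325 to 137693078) and 17q25.2 (chromosome 17 from 75105237 to 75106412), with scores of 717, 672, 571 and 492. By band, 15q26.3 held 9 strong DHT peaks without a partner, and 11q23.2, 22q11.21 and 6p21.31 held 7 each. In 15q26.3, 8 of them lay in 1 cluster (chromosome 15 from 99321741 to 99356684) that also held 4 vehicle peaks, 3 of them shared. The 15q26.3 peak named above lay 2018 bp from the nearest vehicle peak.

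Of the 8 highest-scoring peaks found in the vehicle list alone, 6 are given here. The highest of these was a 5343 bp peak in 8q24.21 (chromosome 8 from 128072237 to 128077579, score 269). 8q24.21 spans 4.2 Mb and is also the band of MYC, and the distance from this peak to MYC was not measured. The other 5 lay in 3q21.3 (chromosome 3 from 128103796 to 128104829 and from 128102162 to 128102744), 12q21.31 (chromosome 12 from 81794838 to 81795354 and from 81775781 to 81776227) and 1p36.33 (chromosome 1 from 564355 to 565441). Their scores lay between 164 and 261. The 2 peaks of 12q21.31 belonged to a cluster of 15 vehicle peaks on chromosome 12 from 81768825 to 81804782 in which the DHT list had 0. The 1p36.33 peak belonged to a tight cluster from 564355 to 570308 of chromosome 1. It held 5 vehicle peaks, all with scores of at least 100, and 1 DHT peak. Peaks in regions prone to artefacts were not filtered out here.

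Many peaks came in clusters, and most clusters covered more sequence in the DHT list. Of 239 clusters of at least 5 peaks, 207 held peaks of both lists, 30 held DHT peaks alone and 2 held vehicle peaks alone. Of the 30, 12 lay within 2 Mb of a heterochromatin band. Of the 2 with vehicle peaks alone, the 1 in 1p12 (chromosome 1 from 120586503 to 120611730) also lay in this zone. The share of 9.16% for DHT peaks taken singly counts another unit, so it is no baseline for clusters. The covered length was greater in the DHT list in 190 of the 239. Beside this, 69.0% of the 1332 shared regions were wider in the DHT list, and the ratio of covered length over all peaks was 1.70. Clusters were formed from both lists pooled. The longer DHT list with its wider peaks therefore favours both this count and that of 30 against 2, in part in advance. The cluster with the most peaks, in 3q22.1 (chromosome 3 from 131935917 to 132066331), had 28 vehicle peaks over 16.0 kb and 42 DHT peaks over 36.8 kb, of which 27 and 20 were shared. The 7p14.1 cluster from 38255363 to 38319763 of chromosome 7 had 28 peaks in each list, covering 13.6 kb after vehicle and 24.6 kb after DHT. In 11q23.2 (chromosome 11 from 113981637 to 114069127), 10 vehicle peaks over 7.11 kb faced 20 DHT peaks over 23.7 kb; this band holds ZBTB16, a zinc finger gene induced by steroid hormones. In 7q21.13 (chromosome 7 from 89821390 to 89864222), the band of the metalloreductase gene STEAP2, 13 vehicle peaks covered 6.58 kb and 15 DHT peaks 14.1 kb. Coverage was lower in the DHT list in 8q24.21 (chromosome 8 from 128015762 to 128116850), with 15 vehicle peaks over 54.2 kb and 7 DHT peaks over 20.7 kb, and in 8q21.11 (chromosome 8 from 75622704 to 75686857), with 20 vehicle peaks over 11.6 kb and 12 DHT peaks over 7.83 kb. Peak widths depend on depth, and none of these differences has a replicate check.

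The kallikrein band 19q13.33, which holds KLK3 (prostate-specific antigen) and KLK2, both classical androgen-induced genes, held a cluster of this kind. On chromosome 19 from 51344618 to 51400329, 8 vehicle peaks covered 7.76 kb, and 7 of them were shared. The DHT list had 15 peaks there over 23.9 kb, 6 shared and 9 without a vehicle partner. The highest-scoring peak of this cluster was shared and lay from 51371233 to 51373485 after vehicle (score 427) and from 51371199 to 51374477 after DHT (score 1798). The cluster in 6p21.31 (chromosome 6 from 35687097 to 35701347) differed in that the vehicle list had 0 peaks and the DHT list 7, over 7.79 kb. For 21q22.3, the band of the androgen-induced protease gene TMPRSS2, values were taken over the whole 5.53 Mb band and not over 1 cluster. There, 34 vehicle peaks (21 shared) covered 25.5 kb and 44 DHT peaks (20 shared) covered 44.2 kb, a ratio near that of the whole lists. The cluster of this band with the most peaks (chromosome 21 from 42891739 to 42908899) had 4 vehicle peaks over 3.2 kb and 4 DHT peaks over 6.5 kb. In 7q33, the band of CREB3L2 itself, there were 16 vehicle and 13 DHT peaks, 0 of them shared, with highest scores of 57.0 and 115. These bands were chosen after their values were seen. A band holds many genes, and no peak was assigned to any of them.

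**Figure D2:**
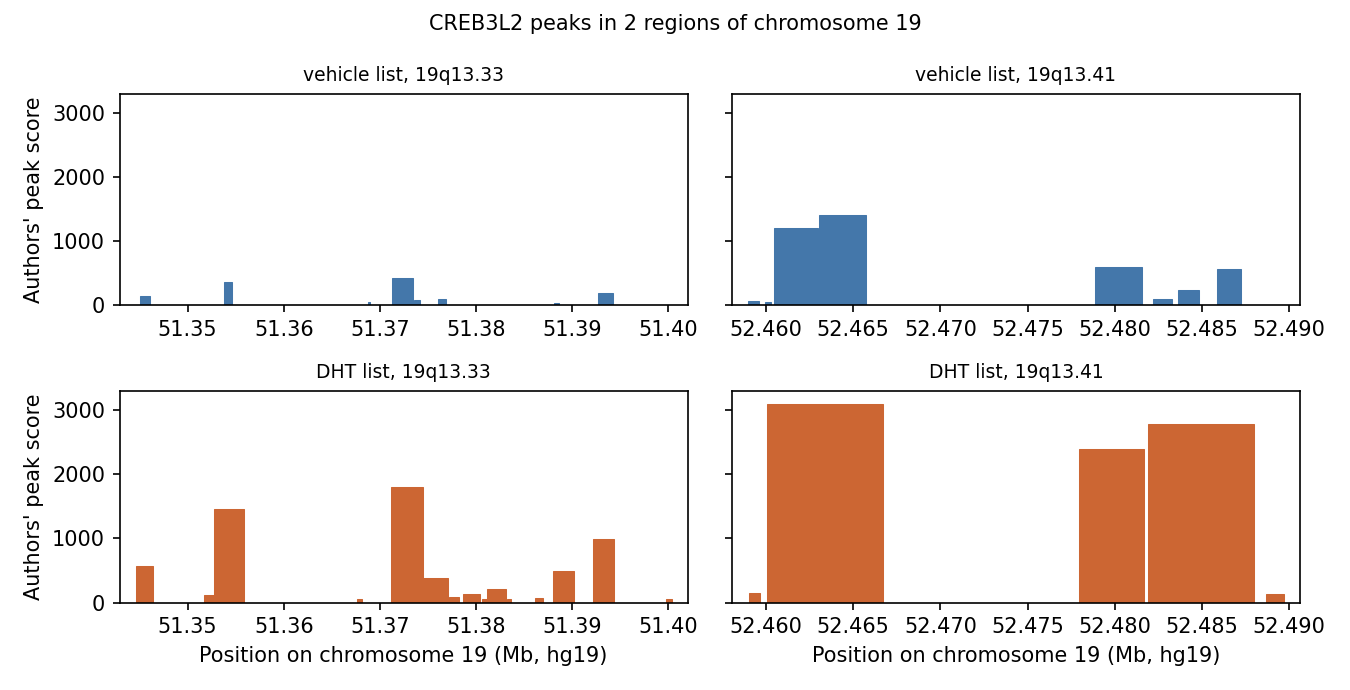
Authors' peak score (y axis) against position on chromosome 19 in hg19 (x axis, Mb) for the vehicle list (top) and the DHT list (bottom), in the clusters of 19q13.33 (left) and 19q13.41 (right); each bar is 1 peak drawn to its width. In 19q13.33 the DHT list has 15 peaks where the vehicle list has 8, and in 19q13.41 the highest bars are 1412 and 3100; heights are not comparable between lists.

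The peaks were spread unevenly over the chromosomes, in a similar way in both lists. Chromosome 8, with 4.73% of the hg19 length, held 9.32% (8.60 to 10.1) of the vehicle and 9.05% (8.44 to 9.71) of the DHT peaks. In both lists most of these peaks lay on the long arm of the chromosome, and the cause of the excess was not tested. Chromosome X, with 5.02% of the length, held 1.16% (0.91 to 1.47) and 1.67% (1.40 to 1.98). The counting intervals of the lists were apart on 3 chromosomes. Chromosome 16 held 38 vehicle peaks (0.66%, 0.48 to 0.90) and 123 DHT peaks (1.59%, 1.33 to 1.89), chromosome 21 held 161 (2.78%, 2.39 to 3.24) and 314 (4.06%, 3.64 to 4.52), and chromosome Y held 13 (0.22%, 0.13 to 0.38) and 43 (0.56%, 0.41 to 0.75). Of these, 5 vehicle and 39 DHT peaks of chromosome 16, 10 vehicle and 76 DHT peaks of chromosome 21, and 7 vehicle and 33 DHT peaks of chromosome Y, lay within 2 Mb of a heterochromatin band. The number of shared peaks on chromosome 16 was 16 of the vehicle and 17 of the DHT list, close by definition because shared peaks overlap each other.

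**Figure D3:**
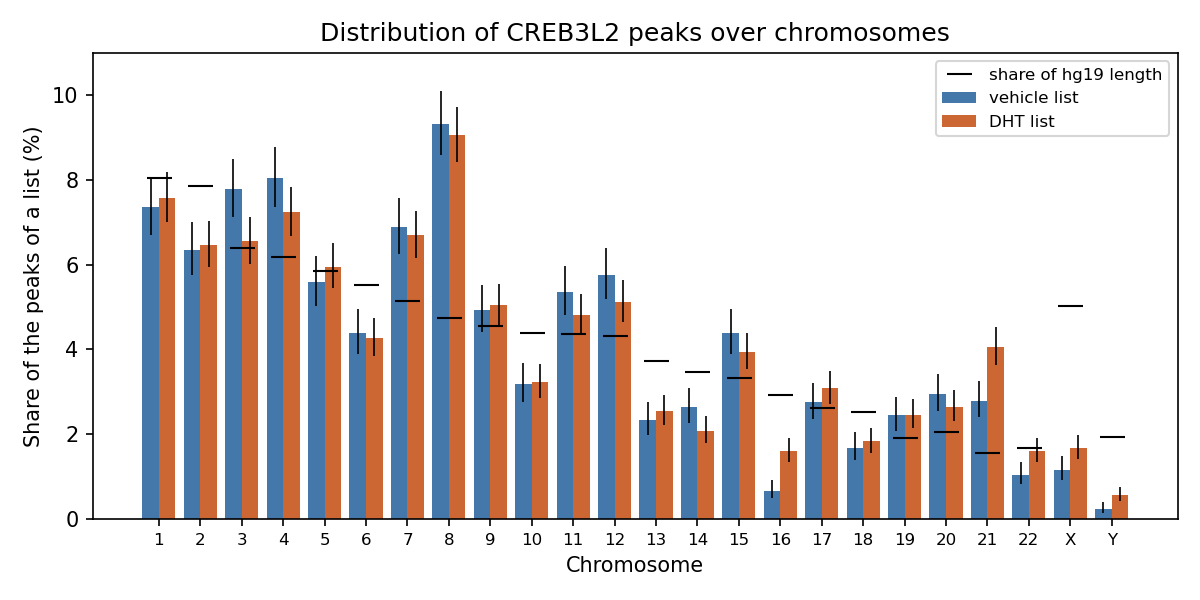
Share of the peaks of each list (y axis, %) on each chromosome (x axis), with Wilson 95% intervals as error bars; the dash is the share of the hg19 length. Chromosome 8 stands at 9.32% and 9.05% against 4.73% of the length, and chromosomes 16, 21 and Y have larger shares in the DHT list.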

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

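Settings by scores of 50 and 100, heterochromatin, dense loci and local moves were chosen after the data were examined. The count of 1438 shared vehicle peaks stayed within 1.5 times its value in all alternatives, between 978 (score at least 50) and 1555 (peaks within 500 bp). The shares moved by more than their counting intervals. For vehicle and DHT peaks they were 17.7% and 13.2% with 50% reciprocal overlap, 19.5% and 14.5% with centres within 200 bp, 26.9% and 19.6% for peaks within 500 bp, 36.5% and 26.1% for the higher-scoring 50% of each list, 43.4% and 24.9% at a score of at least 50, and 23.5% and 22.4% with the DHT list shortened to equal length. For the higher-scoring 50% and for scores of at least 50, both lists were cut before partners were sought. Without dense loci the vehicle share was 22.8%, and the cause was not tested. Leaving out peaks near heterochromatin bands moved neither share by more than its interval, and using all sequence names removed no peak. The overlap was 109 times the chance mean for vehicle and 106 times for DHT peaks with whole-chromosome shuffles, and 46.1 and 45.0 times with local moves, which keep the regional density. Counting peaks within 500 bp as shared lowered the median score of shared peaks beyond its binomial 95% interval, to 66.5 from 69.9 (67.1 to 72.2) for vehicle and to 90.9 from 98.1 (93.3 to 104.3) for DHT, and left the medians of the other peaks within theirs. The shares near heterochromatin bands were 9.25% for vehicle and 15.1% for DHT peaks within 5 Mb, 4.07% and 6.47% outside dense loci, and 3.78% and 6.62% at a score of at least 100, where the intervals overlap. The promoter, gene list and motif alternatives, and shuffles within promoter classes, were not run. No paired analysis was possible because each condition has 1 list. Unknown depth limits every comparison of list length, width and score.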

Other observations

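The tests of random positions, a longer list, a difference between libraries, repeat sequence, copy gain and scores of at least 100 were chosen after the results were seen, as were the zone, the dense loci and the loci named here. The tests of list length, dense loci and weak peaks in that zone were set before their values were seen. Several dense loci held mostly narrow peaks of 1 list. In 21q21.2 (25 to 26 Mb) the DHT list had 17 peaks with a median width of 205 bp, and the vehicle list had 0. In 4q13.1 (64 to 65 Mb) the DHT list had 18 peaks and the vehicle list 4, with 0 shared. In 11q14.3 (89 to 90 Mb) the vehicle list had 17 and the DHT list 4, with 0 shared, and in 12q21.31 (81 to 82 Mb) the vehicle list had 31 and the DHT list 6, with 1 shared. Copy gain at 12q21.31 stays open, because the locus was picked for its 31 and 6 peaks and these counts cannot test it. Band 14q21.1 is that of the forkhead factor gene FOXA1. Its cluster on chromosome 14 from 38035963 to 38068193 held 9 vehicle and 11 DHT peaks, of which 7 in each list were shared. Another cluster of this band, from 37882797 to 37907947, held 3 vehicle and 6 DHT peaks, of which 1 in each list was shared. These clusters are smaller units than the 1 Mb loci above, so they make no contrast with them.

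Most peaks of each list had no partner in the other. Random positions for all weak peaks are argued against, since 6.92% (5.72 to 8.35) of the lowest-scoring 1445 vehicle peaks had a DHT partner, against 0.41% after local moves; that most of these weak peaks are threshold noise stays open. A longer DHT list that contains the whole vehicle list, weak peaks included, is argued against by a bound of 90%. Only 40.8% (39.0 to 42.6) of the higher-scoring 2890 vehicle peaks had a partner in the whole DHT list. That cut reaches down to the median score of 46.9, close to the lowest score of 40, so it cannot decide this for strong peaks. At a score of at least 100, 88.0% (84.8 to 90.6) of the vehicle peaks had a DHT partner. That interval includes the bound of 90%, so for these peaks the explanation stays open. Partners called just beside the peak are too few, at 2.69% (2.25 to 3.22) of the unpartnered vehicle peaks within 500 bp. A response to DHT and a difference between libraries unrelated to DHT cannot be told apart, because there is 1 list per condition.

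DHT peaks lay near heterochromatin bands more often than vehicle peaks: 9.16% (8.54 to 9.82) against 4.50% (3.99 to 5.06), while the zone is 11.1% of the hg19 length, assembly gaps included. List length does not account for it (9.17% in the DHT list shortened to equal length), and a few dense loci are not the whole of it (6.47%, 5.91 to 7.08, against 4.07%, 3.57 to 4.64, outside them). How much dense loci add cannot be read from this, because 42 of the 48 were dense in the DHT list and 13 in the vehicle list. Peaks of a score under 50 alone do not account for it (9.12%, 8.25 to 10.1, against 4.84%, 4.03 to 5.80, at a score of at least 50). At a score of at least 100 the counting intervals of the lists overlapped. Among all such peaks the DHT share of 6.62% (5.32 to 8.21) still lay above the vehicle interval, at 3.78% (2.41 to 5.90). Among the unpartnered ones the difference is unresolved, with 7.89% (5.78 to 10.7) against 7.02% (2.76 to 16.7). Of the unpartnered peaks, 4.12% (3.57 to 4.75) of the vehicle and 9.90% (9.19 to 10.7) of the DHT list lay in the zone. For shared peaks the values were 5.63% (4.56 to 6.95) and 5.72% (4.62 to 7.08). Shared peaks of the 2 lists overlap each other by definition, so these 2 values had to be close and are no separate result. Repeat sequence that reads map to ambiguously is a candidate explanation for the unpartnered DHT peaks in the zone. It stays open because repeat content was not examined, and a DHT response there is untested.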
